A study of Populus tremula x Populus alba with 31 samples.

How the data were processed

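Gene expression was measured in xylem tissue from the base of the stem of a hybrid poplar, Populus tremula x Populus alba, on 2-colour Agilent oligonucleotide arrays. The labels describe wild-type plants and 3 independently transformed lines (3.1, 7.4 and 9.1) that carry EVE1, a gene cloned from Populus trichocarpa, behind the 35S promoter, which drives strong expression in most plant tissues. Plants grew in chambers at 25C or 35C. The labels give plant age as 2 months in one field and 3 months in another.

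The 31 samples are single dye channels of 16 arrays. In 15 arrays both channels are samples, and in 1 array only the Cy3 channel is. The deposited scanner files hold, per the file headers, spot intensity read by Agilent Feature Extraction 10.1.1.1, with foreground, background, processed signal and quality values for 62680 spots. The foreground intensity was deposited without normalisation, and the processed signal was background-subtracted, detrended and dye-normalised by Feature Extraction, per the file headers. A deposited table of log2 values also covers the 31 samples; its making is not stated. Each of its 31 columns had the rank order of 1 channel (Spearman correlation of 1.0, and at most 0.929 with any other channel), but this was the channel of the sample's own scanner file for 4 columns, another sample's channel for 26 and, for 1, the Cy5 channel that belongs to no sample. The sample names of the table and of the scanner files therefore contradict each other. The scanner files, with the dye given in the labels, were used for the results reported, and the table served as an alternative.

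All samples whose growth label reads 25C were on slide 1 and all those whose growth label reads 35C on slide 2, so growth temperature and slide cannot be separated for wild type, line 3.1 and line 7.4. For line 9.1 the title of each sample gives the opposite temperature to its growth label. The samples of line 9.1 therefore entered the average over lines but no comparison within a temperature, and their 2 label sets were compared with each other.

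From the scanner files, mean foreground intensity was corrected by the normexp method with an offset of 50, quantile-normalised over the 31 channels and put on the log2 scale in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Spots that Feature Extraction marked as outliers, 1687 in 1121 probes, were treated as missing. A probe was tested when at least 3 samples of a group were well above background. This left 29889 of 61361 probes, and the probe of highest mean signal stood for each feature, giving 26636 of 49656 features. The share of probes well above background per sample ran from 30.9 to 52.5% and sets the limit for dim transcripts; the number of arrays limits the precision.

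The model had 8 group means and a dye term, with the array as a random block (consensus correlation of -0.0309, estimated on 1 row in 5). All 31 samples entered a single fit, with moderated limma tests and Benjamini-Hochberg adjustment over the features; a feature was called at an adjusted p under 0.05. The p-values measure the spread between the deposited samples. The labels call them biological repeats but say nothing about separate plants, so part of that spread may be technical. On simulated data, the fit for the EVE1 average recovered 90% of 50 features changed by log2 0.5 and 100% of 50 changed by log2 1, with 11 false calls among unchanged features of the 26636. For line 3.1 alone it recovered 72% at log2 0.5 and 98% at log2 1, and for the EVE1 effect at 25C 60% and 94%. The simulated noise was independent between features and of equal size in all groups, so these shares may overstate recovery in the real samples. The simulated changes were the same at both temperatures and so held no interaction; the interaction test called 0 of the changed features and 0 others.

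The groups, the model, most alternatives and 29 gene lists were fixed before the data were examined. The files pair no feature with a gene name or function and no reference was used here, so none of the 29 lists had a measured member and the planned rule for named genes, which required an annotated function, selected nothing. In its place, the 2 largest rises and 2 largest falls among the called features were taken, for the averages only features with the same direction in each line or genotype. All of these are named for the EVE1 average, the average temperature effect, the EVE1 effect at each temperature and the interaction, and only some of them for single lines, wild type temperature, the sets of line 9.1 and the differences between lines. This rule was chosen after the files had been seen. Features are given by the identifiers of the files.

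To describe gene groups, probes were translated in 3 frames (biopython 1.88) and matched to peptide motifs typical of protein families. The 31 motif classes were written after the missing annotation had been noticed. Their patterns were revised on counts of matches and of chance matches in reversed probes, through 3 versions, before the expression of the matching features was looked at. The choice to test the classes pooled into sets was made after fold changes of members had been seen. A match in a 60-base probe is weak evidence of identity. The 6 sets with at least 3 measured features (heat shock 3, cell wall 5, cytoskeleton 5, cell division 8, transcription regulators 6, housekeeping 9) were tested in 9 comparisons, 54 tests in all, by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 6 sets of a comparison. Camera took only features without a missing value, which left 4 of the 5 cytoskeleton and 7 of the 8 cell division features. Each set's median was also placed among 10000 random sets matched on mean signal.

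Alternatives covered background correction, normalisation, the deposited table under both of its readings, the filter, the dye term, the array block, a replicate block, the treatment of several probes, the variance model, the handling of line 9.1, the slide, outlier spots and leaving out each sample in turn. Figures were drawn with matplotlib 3.10.9.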

Results

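Transcript levels were measured in stem xylem of hybrid poplar in 31 samples: 4 wild-type samples at each of 25C and 35C, 4 of line 3.1 at each temperature, 4 of line 7.4 at 25C and 3 at 35C, and 8 of line 9.1 in 2 sets of 4 whose titles and growth labels give opposite temperatures. The mean share of probes well above background ranged from 36.8% in line 7.4 at 35C to 47.8% in line 3.1 at 25C, and was 42.6% and 42.4% in wild type at 25C and 35C.

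The comparison of all 3 EVE1 lines with wild type asks what overexpression of EVE1 changes in xylem. A single transcript changed by far more than the others. POPTR_0001s33660.1 was 41.9-fold higher in the transgenic lines (log2 5.39 ± 0.21 SE, limma adjusted p = 2.85e-15), at a mean log2 signal of 16.43 ± 0.44 (SD, n = 23) against 11.03 ± 0.74 (SD, n = 8) in wild type. POPTR_0017s09915.1 rose by log2 1.75 ± 0.07 SE (limma adjusted p = 4.54e-15). It was well above background in 3 of 8 wild-type and 23 of 23 transgenic samples, so the size of its rise is limited by the floor of the array here and in every comparison with wild type below. Over the alternatives its log2 change ran from 0.65 with the deposited table as named to 4.23 with the processed signal. For both features all 23 transgenic samples lay above the highest wild-type sample. POPTR_0006s12905.1 fell by 0.92 ± 0.16 SE on the log2 scale (limma adjusted p = 0.014), with 12 of 23 transgenic samples below the lowest wild-type sample, and POPLARP022243 fell by 0.67 ± 0.10 SE (limma adjusted p = 0.00263), with 16 of 23 below it. For the latter 0 of 3 samples of line 7.4 at 35C were well above background, which limits the size of its fall. With the array as a fixed block neither fall was called: the log2 change was -0.94 for POPTR_0006s12905.1 (limma adjusted p = 0.210, and 0.00172 to 0.988 over the alternatives) and -0.65 for POPLARP022243 (limma adjusted p = 0.551, and 0.000241 to 0.988). The highest limma adjusted p of each, 0.988, came from the deposited table as named, whose sample names contradict the scanner files. POPTR_0006s12905.1 also lost its call in 2 of 31 fits that left out a single sample (highest limma adjusted p of 0.0655). Of its 3 probes 1 passed the filter and was tested, and 2 of 23 transgenic samples lay above the highest wild-type sample. The files do not say which feature is EVE1.

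Of 26636 features, 9 were called in this comparison by limma, 6 higher and 3 lower, and 1975 had an unadjusted p under 0.05. With samples left out in turn the unadjusted count ran from 1008, without wild type at 25C replicate 2, to 2920. Without line 9.1 limma called 21 features (14 higher, 7 lower), and with the array as a fixed block 4 (4 higher, 0 lower; 778 at an unadjusted p under 0.05). None of the 6 motif sets passed camera after adjustment. The members of the cell wall set had a median log2 change of -0.01 and those of the heat shock set 0.15. That heat shock median stood at the 99.4 percentile of random sets matched on signal (camera adjusted p = 0.522). No member of any set was called. The 3 probes of each leading feature overlapped almost entirely in sequence, so they are not independent readings. Read from the deposited log2 table with its columns as named, limma called 0 features, with 1309 at an unadjusted p under 0.05. With that table's columns given to the samples whose scanner files match them, all 4 named features were called again.

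**Figure D1:**
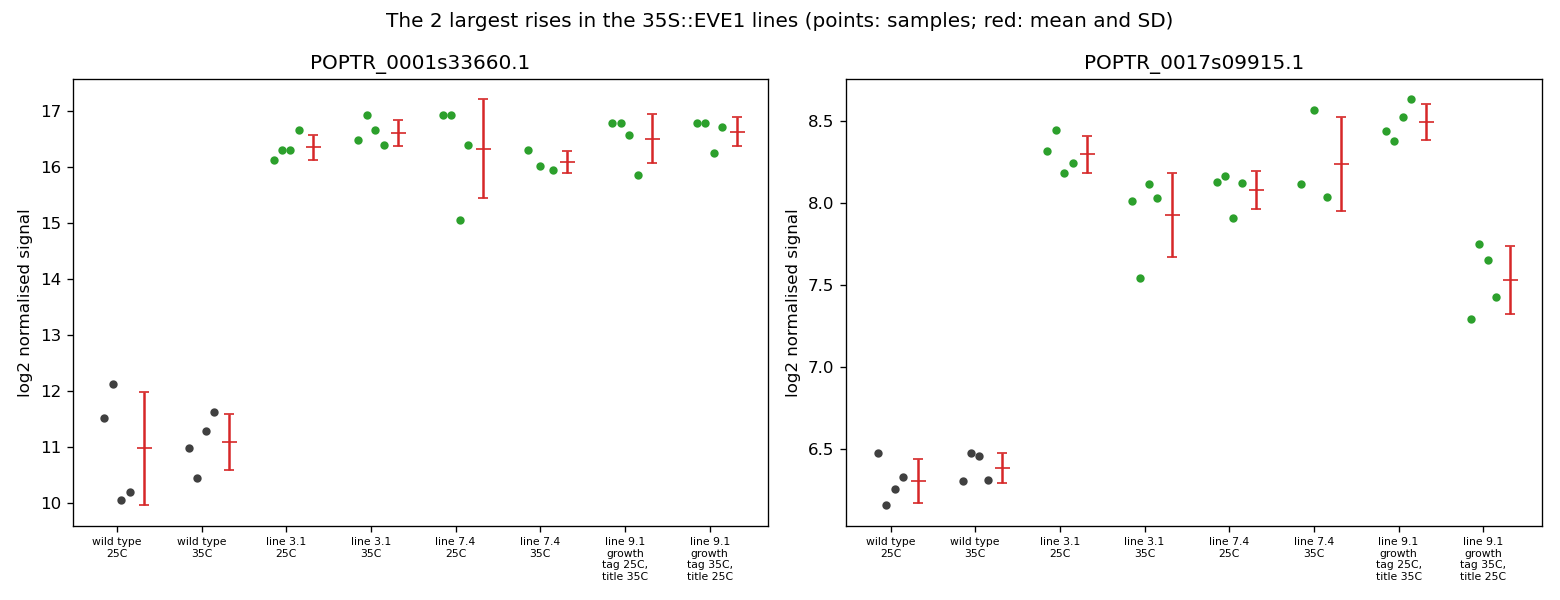
Log2 normalised signal of POPTR_0001s33660.1 and POPTR_0017s09915.1 in each sample by group, with wild type in grey, the EVE1 lines in green, and the mean and SD of each group in red. All 23 transgenic samples lie above the highest of the 8 wild-type samples for both features.

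Taken line by line, the same 2 features led the rises in each line. POPTR_0001s33660.1 was higher by log2 5.44 ± 0.26 SE in line 3.1, 5.20 ± 0.27 SE in line 7.4 and 5.53 ± 0.26 SE in line 9.1. Several transgenic samples held exactly the same value for POPTR_0001s33660.1, such as 16.92 or 16.79, since quantile normalisation gives equal ranks equal values. The likeness of the lines may thus be partly set by the normalisation. Over the alternatives the average log2 rise of POPTR_0001s33660.1 ran from 1.76 to 5.61. POPTR_0017s09915.1 was higher by log2 1.76, 1.81 and 1.66 in the same lines, with wild type well above background in 1 of 4 samples at 25C and 2 of 4 at 35C. In line 9.1 the set with growth label 35C differed from the other by log2 -0.97 for this feature (limma adjusted p = 5.08e-07). Between the slides it changed by -0.37 in line 3.1 (limma adjusted p = 0.0276) and by 0.15 in line 7.4, which was not called. POPTR_0006s12905.1 fell by 1.74 on the log2 scale in line 3.1, the largest called fall in that line. Its changes of -0.53 in line 7.4 (limma adjusted p = 0.404) and -0.49 in line 9.1 (limma adjusted p = 0.366) were not called. Its mean log2 signal was 7.21 in the line 9.1 set with growth label 25C and 9.39 in the other. These 2 sets differed by log2 2.19 (limma adjusted p = 3.16e-07). Wild type averaged 8.39 at 25C and 9.21 at 35C. Altogether 4 features were called higher in all 3 lines and 0 lower. In 100 simulations of unchanged lines in the same design, with wild type simulated too, the count was at most 0. The simulated noise was independent between features and alike in all groups, which the real samples need not be. Other splits of the real samples gave at most 1. The other two of the 4 rose by log2 0.82 and 0.68 on average; they were well above background in 0 of 8 wild-type and 23 of 23 transgenic samples, so their change is limited by the floor of the array too.

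Limma called 16 features in line 3.1 (9 higher, 7 lower), 21 in line 7.4 (17 higher, 4 lower) and 8 in line 9.1 (7 higher, 1 lower). Across features, which are not independent replicates, the changes of lines 3.1 and 7.4 had a Pearson r of 0.572. Simulated unchanged lines that share their simulated wild-type samples gave 0.479. For lines 3.1 and 9.1 r was 0.450 beside 0.501 simulated, and for lines 7.4 and 9.1 0.047 beside 0.479. The covariance exceeded the simulated one by 0.00873 and 0.00445 for the pairs with line 3.1 and differed from it by -0.00622 for lines 7.4 and 9.1. With the wild-type samples split so that no control was shared, r was 0.134 and 0.236 for lines 3.1 and 7.4, 0.00950 and 0.137 for lines 3.1 and 9.1, and -0.209 and -0.182 for lines 7.4 and 9.1. With samples left out in turn, the count of line 3.1 ran from 7 to 23 (7 without line 3.1 at 35C replicate 4 or wild type at 35C replicate 1, 8 without wild type at 25C replicate 2, 10 without line 3.1 at 25C replicate 3). That of line 7.4 ran from 13 to 42 (13 without line 7.4 at 35C replicate 1, 32 without line 9.1 with growth label 35C replicate 2, 37 without line 3.1 at 35C replicate 1, 42 without wild type at 35C replicate 3). The count of line 9.1 ran from 6 to 231 and was 231 without replicate 2 of the set with growth label 35C, 129 without line 3.1 at 35C replicate 1, 14 without replicate 2 of that group, and 19 and 20 without wild type at 35C replicates 1 and 4. Its balance of directions changed as well: 205 higher and 26 lower in the fit that called 231, 25 higher and 104 lower in the fit that called 129, and 9 higher and 20 lower with the processed signal.

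The comparison of 35C with 25C asks how growth temperature changes the xylem transcriptome, and it is also a comparison of slide 2 with slide 1. Differences were broad. In wild type, most cell wall features were lower on the 35C slide: a fasciclin-like feature fell by 2.05 on the log2 scale, a laccase feature, of the family that oxidises lignin precursors, by 1.90, and 2 cellulose synthase features by 1.64 and 0.38. All 5 cytoskeleton features fell, 4 matching tubulin, the subunit of microtubules, by 0.37 to 1.99 and 1 matching actin by 0.47. The 3 heat shock features, 2 matching small heat shock proteins and 1 HSP70, had log2 changes of 0.32, 0.59 and -0.13, and none was called.

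In wild type the cell wall set fell in 4 of 5 members, with a median of -1.64 (camera adjusted p = 0.00293; adjusted p = 0.140 with an estimated correlation). The cytoskeleton set fell in 5 of 5 members, with a median of -0.84 (camera on the 4 members without a missing value, adjusted p = 0.00293; adjusted p = 0.140 with an estimated correlation). Among 10000 random sets matched on signal these medians stood at the 0 and 0.36 percentile, and the heat shock median of 0.32 at the 95.41 percentile (camera adjusted p = 0.447). Of 9 housekeeping features 5 fell and 0 rose, all 5 matching ubiquitin. Of 6 regulator features 2 fell, with log2 changes of -1.67 in a NAC and -1.37 in an R2R3 MYB, and an R2R3 MYB rose by 0.25. The same 2 sets were low in line 3.1, where the cell wall median was -1.50 and the cytoskeleton median -1.15, and in line 7.4, where they were -0.83 and -0.95. In line 7.4, 2 of 5 cell wall features fell (camera adjusted p = 0.204).

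**Figure D2:**
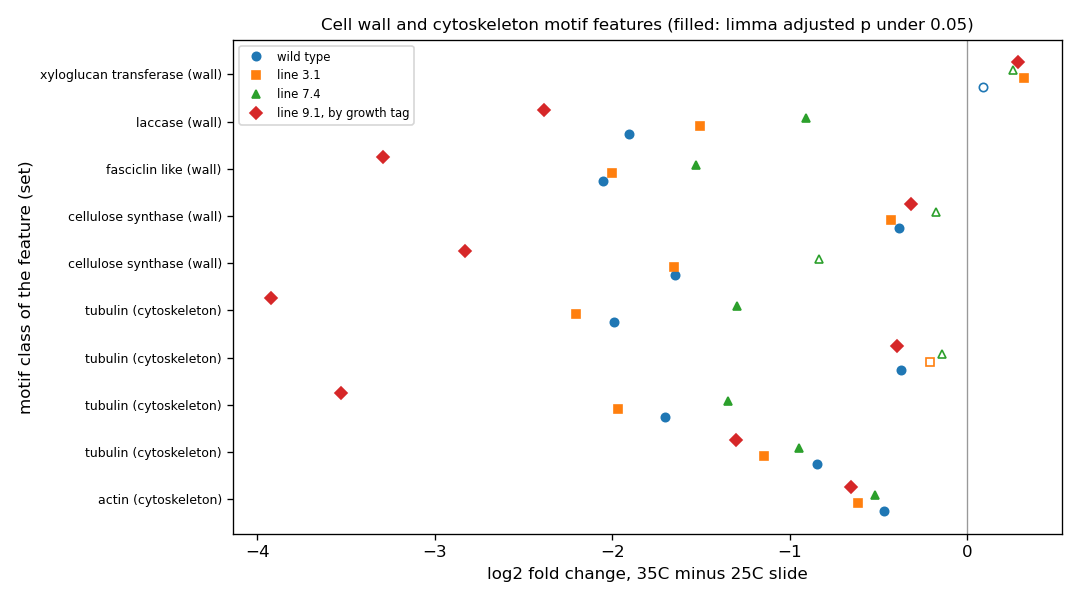
Log2 fold change between the slide with growth label 35C and the slide with growth label 25C for the 5 cell wall and 5 cytoskeleton motif features, in wild type, lines 3.1 and 7.4, and line 9.1 by growth label. Filled points have a limma adjusted p under 0.05; all 5 cytoskeleton features fell in wild type and 4 of 5 cell wall features did.

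Averaged over wild type and lines 3.1 and 7.4, POPLARP016835 rose by log2 5.20 ± 0.35 SE (limma adjusted p = 3.13e-11) and POPLARP132255 by 4.71 ± 0.29 SE (limma adjusted p = 8.82e-12). POPLARP087059 fell by 3.64 ± 0.47 SE (limma adjusted p = 4.87e-07) and POPLARP304304 fell by 3.42 ± 0.23 SE (limma adjusted p = 3.13e-11). In wild type POPLARP016835 went from a mean log2 signal of 6.71 ± 0.20 (SD, n = 4) at 25C to 13.12 ± 1.06 (SD, n = 4) at 35C, and POPLARP304304 from 11.19 ± 0.40 (SD, n = 4) to 7.05 ± 0.17 (SD, n = 4). At 25C POPLARP016835 was well above background in 3 of 4 samples of wild type and 1 of 4 of line 7.4, which limits the size of its rise. Limma called 7783 features in wild type (3667 higher, 4116 lower) and 12629 in the average (5782 higher, 6847 lower). The heat shock set had 2 of 3 members called higher in the average, with a median of 0.31 (camera adjusted p = 0.182). Wild type and line 3.1 shared 5113 called features, all 5113 in the same direction, where independent lists would share 388 rises and 665 falls; their changes had r = 0.863 across features. Wild type and line 7.4 shared 2831, of which 2824 went the same way. No sample of wild type, line 3.1 or line 7.4 with the same temperature label was on the other slide, so no value within a slide can be given.

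The EVE1 effect within each temperature, in lines 3.1 and 7.4, asks whether the transgene acts alike in cool and warm plants. At 25C the same 2 features rose, POPTR_0001s33660.1 by log2 5.34 ± 0.32 SE and POPTR_0017s09915.1, limited by the floor, by 1.88 ± 0.11 SE. POPLARP003830 fell by 1.91 ± 0.28 SE (limma adjusted p = 0.00278), from 9.33 ± 0.35 (SD, n = 4) in wild type to 6.75 ± 0.38 (SD, n = 4) in line 3.1 and 8.05 ± 0.54 (SD, n = 4) in line 7.4, and POPLARP199301 fell by 1.64 ± 0.18 SE (limma adjusted p = 1.72e-05). At 35C POPTR_0001s33660.1 rose by log2 5.29 ± 0.33 SE and POPTR_0017s09915.1, limited likewise, by 1.69 ± 0.11 SE. The largest falls among the called features there were POPLARP001105 and POPLARP055200. Their log2 changes were -1.98 ± 0.36 SE (limma adjusted p = 0.0172) and -1.71 ± 0.32 SE (limma adjusted p = 0.019). Mean log2 signal of POPLARP001105 at 35C was 9.73 ± 1.19 (SD, n = 4) in wild type. It was 8.38 ± 0.88 (SD, n = 4) in line 3.1 and 7.10 ± 0.72 (SD, n = 3) in line 7.4. There the feature was well above background in 2 of 3 samples, which limits the size of its fall. For POPLARP055200 these means were 10.5, 9.4 and 8.1. In the line 9.1 set with growth label 35C, outside this comparison, both features lay above wild type, at 10.35 and 11.4. POPLARP001105 rose between the slides by log2 3.50 in wild type, 2.15 in line 3.1 and 0.88 in line 7.4. POPLARP055200 rose by 3.43, 2.36 and 0.85, and neither rise was called in line 7.4. The falls at 35C are thus also smaller rises between the slides in the EVE1 lines. Mean values on the first principal component at 35C were 40.2, 33.8 and 12.6 in wild type, line 3.1 and line 7.4. Whether EVE1 or a weaker shift of line 7.4 lies behind the falls was not tested. The SD of POPLARP001105 in wild type was 0.14 at 25C, so an SE pooled over all groups may be too small at 35C.

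Limma called 6 features at 25C (4 higher, 2 lower; 2717 at an unadjusted p under 0.05) and 27 at 35C (7 higher, 20 lower; 2871 unadjusted). With samples left out in turn, the unadjusted count at 25C ran from 536 without wild type at 25C replicate 2 to 4218 without replicate 4 of that group. With line 9.1 added by growth label limma called 6 at 25C and 5 at 35C (4 higher, 1 lower). Line 9.1 added by title instead gave 2355 at 25C, 2708 at 35C and 5532 for the difference between temperatures. With the array as a fixed block limma called 4 at 35C (3 higher, 1 lower). The count at 35C ran from 9 without wild type at 35C replicate 1 to 237 without line 3.1 at 35C replicate 1 when samples were left out in turn, and 9 of the 31 samples moved it by over 1.5 times. In the test of the difference between temperatures POPLARP199301 was the 1 feature called by limma, with a log2 difference of 1.92 ± 0.26 SE (adjusted p = 0.00236, and 2796 features at an unadjusted p under 0.05). Its mean log2 signal was 8.56 ± 0.55 (SD, n = 4) in wild type at 25C, and 0 of 4 wild-type samples and 0 of 4 line 3.1 samples at 35C were well above background, so wild type at 35C was at least 4.32-fold lower and the difference is limited by the floor. Over the alternatives its log2 difference ran from 0.55 to 3.70 and its limma adjusted p from 4.24e-06 to 0.737. It was not called at 0.55 with the deposited table as named or at 3.70 with the processed signal. The count of 1 ran to 5, without wild type at 35C replicate 3, when samples were left out in turn, and the unadjusted count from 1458, without wild type at 25C replicate 2, to 3525. In the same test the regulator set had a median of 0.34 and the cell wall set of 0.29 (both camera adjusted p = 0.0481; adjusted p = 0.265 and 0.406 with an estimated correlation), with 0 members called in either. At 35C the 5 cell wall features had a median log2 difference of 0.20 between the EVE1 lines and wild type (camera adjusted p = 0.0262; adjusted p = 0.491 with an estimated correlation), and 0 of 5 was called.

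The 2 sets of line 9.1 differed much as the 2 slides differed in wild type. With the set of growth label 35C (title 25C) set against the other, POPLARP016835 was higher by log2 7.94 ± 0.60 SE (limma adjusted p = 5.87e-10; well above background in 2 of 4 samples of the other set), 4 of 5 cell wall features fell, with a set median of -2.38, and 5 of 5 cytoskeleton features fell, with a median of -1.30. The fifth cell wall feature, a xyloglucan transferase, rose by log2 0.29 (limma adjusted p = 0.0223). The 1 feature matching a chlorophyll-binding protein, which marks green tissue, rose by 1.66 (limma adjusted p = 1.83e-05). Its log2 change between the slides was 0.83 in line 3.1, where it was called, and 0.58 in wild type and -0.49 in line 7.4, where it was not. How much green tissue the samples held was not measured. The heat shock features had a median of 0.61, and 2 of 3 were called higher. Limma called 11649 features (5669 higher, 5980 lower). Of these, 6568 were called in wild type as well, all in the same direction, and r across features was 0.890. The set with growth label 35C was on slide 2 and the other on slide 1.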

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

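The within-array test, both tests of the line 9.1 labels and all counts of other splits were chosen or written after related results had been seen. The heat shock tests of the slide and of brightness, and the test over classes of signal, were written before their values were seen.

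The first pattern is the broad difference between 35C and 25C, 7783 features in wild type. After normalisation the change did not follow brightness: 20 classes of mean signal accounted for 0.328% of its variance over these features. Quantile normalisation evens out shifts that follow signal level, so a low share would arise either way. The test therefore cannot decide on brightness as the whole cause. The tests written beforehand did not separate temperature from slide: the 3 heat shock features had a median of 0.32 in wild type, at the 95.41 percentile of random sets matched on signal and inside the range that a slide effect or brightness would give, and stood at the 99.44 percentile in line 3.1, outside it, at the 95.01 in line 7.4, inside it, and at the 97.54 in the average, just outside it. In the within-array test, samples sharing an array on slide 2 lay a median of 16.54 apart on the first principal component. On 3 of 7 arrays, at 47.1, 47.1 and 68.4, they lay beyond the largest distance of 17.1 on slide 1. The median stayed under that bound, so the test did not decide. Samples that share an array also differ in dye, and the distances do not bear on the step between slides. Temperature and slide cannot be told apart, because every sample with growth label 35C was on slide 2. A response of wall and cytoskeleton genes to warmth therefore stays a hypothesis. Samples of both temperatures on the same slide would be needed to test it.

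The second pattern is line 9.1, whose titles and growth labels give opposite temperatures. The heat shock features were higher in the set with growth label 35C by a median of 0.61, at the 98.21 percentile of matched random sets, the direction that the growth labels predict and the titles do not. These are 3 features, and the growth label coincides with the slide here too. Between the slides the same set left the random range in line 3.1 and the average (99.44 and 97.54 percentile). It did not do so in wild type or line 7.4 (95.41 and 95.01). The set also left the range in the EVE1 average (99.4), where both temperatures count alike, and in the interaction (98.65). Whether titles or growth labels give the temperature cannot be told apart, since a slide effect could give the same direction.

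Other groupings of the same samples were refitted to see how often they gave as many called features. The real grouping is counted among the splits, so 1 of 100 or 1 of 35 means that no other split gave as many. For the EVE1 average 3 of 100 splits gave as many as the 9 features called (highest other 770). For the features called in all 3 lines 1 of 100 did (4 called, highest other 1). It was 3 of 100 for line 3.1 (16 called, highest other 664) and 3 of 100 for line 7.4 (21 called, highest other 326). The EVE1 effect at 25C had 1 of 100 (6 called, highest other 4). The average temperature effect had 1 of 100 (12629 called, highest other 8724) and wild type temperature 1 of 35 (7783 called, highest other 237). The 2 sets of line 9.1 had 1 of 35 (11649 called, highest other 2108). Lines 3.1 and 7.4 had 3 of 100 (10 called, highest other 88), and lines 7.4 and 9.1 had 2 of 100 (1648 called, highest other 1697). Chance cannot be excluded for line 9.1 against wild type (8; 12 of 100, highest other 1218), for the EVE1 effect at 35C (27; 13 of 100, highest other 1042), for the interaction (1; 8 of 100, highest other 330) or for lines 3.1 and 9.1 (25; 9 of 100, highest other 287). The shares were not adjusted over the comparisons, so 2 or 3 of 100 does not exclude chance either. Where no other split reached the real count, the real grouping called more features than every other split drawn. Splits that called many times the real count point to a structure among the samples. What these splits line up with was not tested.

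Effects that differed between groups by limma were the interaction of EVE1 with temperature in 1 feature, lines 3.1 and 7.4 in 10, lines 3.1 and 9.1 in 25, and lines 7.4 and 9.1 in 1648. The temperature effect differed from wild type in 14 features in line 7.4 and, by growth label, in 4 in line 9.1; in line 3.1 limma called 0, with 1267 at an unadjusted p under 0.05.

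Single samples lay far from the other 3 of their group in 12 of 152 tests, each of 1 feature or measure in 1 group. Chance gives about 1 in 20 for a single test. The tests share samples and are not independent, so the count of 12 cannot be set against that rate. In the line 9.1 set with growth label 35C, replicate 2 was low for POPLARP016835 at 13.13 (others 14.76 to 15.01), POPLARP016828 at 12.21 (14.10 to 14.22), POPLARP132255 at 12.60 (14.36 to 14.41), POPLARP001105 at 9.39 (10.60 to 10.74) and POPLARP055200 at 10.33 (11.66 to 11.86). Replicate 3 of that set stood apart at 7.63 for POPLARP003830 (6.30 to 6.40), at 16.24 for POPTR_0001s33660.1 (16.71 to 16.79) and at 75.6 on the first principal component (69.0 to 69.9). In the other set of line 9.1, replicate 2 was high for POPLARP132255 at 7.89 (7.10 to 7.14). Line 3.1 at 35C replicate 1 was low for POPLARP129198 at 8.59 (others at most 9.08), line 7.4 at 25C replicate 3 was low for POPTR_0017s09915.1 at 7.91 (8.12 to 8.16), and wild type at 25C replicate 2 had 35.9% of probes well above background (44.6 to 45.2%).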

How the results depend on the processing

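Outlier spots kept and the deposited table with its columns given to the matching scanner channel (30 samples) were alternatives chosen after seeing the data, as were the motif sets. Leaving out each of the 31 samples in turn gave 7 to 13 features for the EVE1 average, 7 to 23 for line 3.1, 13 to 42 for line 7.4, 6 to 231 for line 9.1, 4 to 6 at 25C, 9 to 237 at 35C, 1 to 5 for the interaction, 4 to 4 in all 3 lines, 6444 to 8081 for wild type temperature, 11476 to 13132 for average temperature and 10445 to 12114 for the sets of line 9.1. Line 3.1 moved by over 1.5 times without line 3.1 at 25C replicate 3 (10), line 3.1 at 35C replicate 4 (7), wild type at 25C replicate 2 (8) and wild type at 35C replicate 1 (7). Line 7.4 did so without line 3.1 at 35C replicate 1 (37), line 7.4 at 35C replicate 1 (13), line 9.1 with growth label 35C replicate 2 (32) and wild type at 35C replicate 3 (42). Line 9.1 did so without line 3.1 at 35C replicates 1 (129) and 2 (14), line 9.1 with growth label 35C replicate 2 (231) and wild type at 35C replicates 1 (19) and 4 (20). The 35C count did so without line 3.1 at 35C replicates 1 (237) and 4 (56), line 7.4 at 35C replicate 1 (14), line 9.1 with growth label 35C replicates 2 (129) and 3 (47), and wild type at 35C replicates 1 (9), 2 (83), 3 (111) and 4 (11). The interaction did so without line 3.1 at 35C replicates 1 (3) and 4 (2), line 7.4 at 35C replicate 3 (3), wild type at 25C replicate 3 (2), and wild type at 35C replicates 3 (5) and 4 (3). POPTR_0006s12905.1 lost its call without wild type at 25C replicate 3 (-0.92) and without wild type at 35C replicate 4 (-0.86), with a highest limma adjusted p of 0.0655. The cause of the changes below was not tested unless stated.

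With the deposited table as named, limma called 0 features for the EVE1 average, each line, all 3 lines, both temperatures and the interaction, with 1309, 765, 1462, 1202, 1250, 2052 and 2095 at an unadjusted p under 0.05 for the average, lines 3.1, 7.4 and 9.1, 25C, 35C and the interaction; its sample names contradict the scanner files. With its columns given to the matching channels, line 7.4 had 13 and line 9.1 had 21. The strict filter, which tests fewer features, gave 3 for the average, 6, 4 and 5 for lines 3.1, 7.4 and 9.1, 1 in all 3 lines, 1 at 25C, 7 at 35C, 4841 for wild type temperature, 7569 for average temperature, 7108 for the sets of line 9.1, and 0 for the interaction in limma, with 1333 unadjusted. The array as a fixed block gave 4 for the average, where POPTR_0006s12905.1 (-0.94) and POPLARP022243 (-0.65) lost their calls, 9, 3 and 4 for the lines, 4 at 35C and 2 for the interaction. The processed signal gave 10 for line 3.1, 29 for line 9.1, 43 at 35C and 0 for the interaction in limma, with 3065 unadjusted. Without background correction line 9.1 had 19 and 35C 51. The mean of several probes gave 14 for line 9.1, the loess and separate-channel fit 8 for line 3.1 and 14 at 35C, and the trended, robust variance 2 for the interaction. Without line 9.1 the average had 21. Adding line 9.1 by growth label gave 5 at 35C. Adding it by title gave 2355 at 25C, 2708 at 35C, 2810 for average temperature and 5532 for the interaction, and with the slide as a fixed block 1155 for average temperature. That slide block could be fitted only because line 9.1 was read by its disputed titles. The 1155 therefore do not separate temperature from slide.

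The replicate block gave 32 for line 7.4, 71 at 35C and 4 for the interaction, and moved no other count by over 1.5 times. The numbers do not pair the samples. After the group means were subtracted, samples of different groups with the same number had a median correlation of -0.0402 over 105 pairs. It was -0.0016 over 315 pairs with different numbers, and 3 of 31 samples correlated best with a sample of their own number. Over all alternatives the limma adjusted p of POPTR_0001s33660.1 ran from 4.10e-17 to 0.988 and that of POPTR_0017s09915.1 from 6.03e-16 to 0.988. Each lost its call in 1 alternative only, the deposited table as named, whose sample names contradict the scanner files. Leaving out single samples gave at most 6.90e-14 and 1.06e-13 by limma. Dim transcripts limit the results, since 15358 probes were well above background in all samples.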

Other observations

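The probe overlap test was written after the probes had been seen to be alike; the test of neighbouring features was written before its value was seen.

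Single features of other motif classes were called in some genotypes and not in others. A chitinase feature, of a family of defence proteins, rose by log2 0.42 in wild type and by 1.14 between the 2 sets of line 9.1, and was not called in lines 3.1 (0.37) and 7.4 (0.18), but was called in the average over these and wild type (0.32). The 1 class III peroxidase feature tested, of 7 matched, rose by 0.83 in wild type and 1.44 between the sets of line 9.1, and was not called in line 3.1 (0.38), line 7.4 (-0.26) or the average over these and wild type (0.32). A WRKY regulator feature rose by log2 3.04 in line 7.4 and by 1.41 in the average, and was not called in wild type (0.34), line 3.1 (0.85) or line 9.1 (0.26). The histone features, made in dividing cells, had a median of -0.05 in wild type with 1 of 8 called lower, and of -0.41 between the sets of line 9.1 with 5 of 8 called lower. None of these features was called by limma in the interaction of EVE1 with temperature over lines 3.1 and 7.4. These classes were described after their values had been seen.

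In line 7.4, 5 of the 17 features called higher had identifiers numbered close to one another, 3 under scaffold number 3 and 2 under scaffold number 200. They were higher by log2 0.64 to 0.97, against 0.00 to 0.09 in line 3.1 and 0.06 to 0.19 in line 9.1. A candidate explanation is one transcript read by near-identical probes: the median longest run of bases that a probe shared with another of the group was 29, and 4 of the 5 shared at least 25, where 200 random pairs shared at most 14. Activation around an insertion site in line 7.4 stays open, since 1 other tested feature lay within 10 numbering steps; it had a log2 change of 0.41, at the 96.54 percentile of random neighbours, and a single feature decides nothing.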
